A study of Halobacterium salinarum NRC-1 with 23 samples.

How the data were processed

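Halobacterium salinarum NRC-1 is a salt-loving archaeon, and the strain studied lacks pyrF (also called ura3), the gene for orotidine 5'-phosphate decarboxylase, the last enzyme of UMP synthesis. Per the labels, the strain grew with 20 µg/ml uracil at 37 °C, and RNA was taken at 6 time points from 690 to 3120 min. Total RNA of each culture sample was hybridised together with a common reference RNA on 2-colour arrays of 70-base oligonucleotides, with the dyes Alexa 546 and Alexa 647. There were 23 arrays of 12 culture samples, 2 samples per time point. For 11 samples the arrays formed a dye-swapped pair, and the second sample of 690 min had a single array. Samples were grouped by the time in the labels, and the arrays of one sample were recognised by a shared optical density. Replicate numbers 1 and 2 only name the samples, in the order of deposit. The series text speaks of duplicate flasks but ties no sample to a flask, so the p-values measure the spread between these samples, which may be partly technical. The labels call the reference a mid-log NRC-1 culture, whereas the series text calls it the final time point of a repeated experiment, so each ratio is given only as culture over reference.

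Spot brightness is an intensity on a linear scale in the deposited scanner files, which the authors left unnormalised, with a local background for each spot and dye. The series table deposited by the authors holds log10 ratios, made with error-model lambda values per the series text. Tool names and versions for that step are not given in the sources used here. The table's spots matched the scanner spots when counted in reading order across the slide. Over spots brighter than 1000 above background in both dyes, the authors' ratios then correlated with the scanner ratios at r = 0.900 to 0.987 per array, against -0.018 to 0.107 when matched by spot number. The medians of the authors' columns lay between -0.038 and 0.108. This comparison settles their spot order and their orientation by dye. It cannot settle their log10 scale, since a correlation does not depend on the base of the logarithm. How they were centred stays unknown. All 23 columns of the authors' values were used, and 0 columns were left unassigned.

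Each array held 10752 spots, 4 for each of 2688 oligos. The platform annotation supplied here gave 133 oligos exactly 1 gene symbol, 0 oligos several symbols and 2555 none, and control oligos could not be told from the unnamed ones. All 133 symbols were found in the gene table of strain 91-R6, which served only to find neighbouring genes. Results for unnamed oligos are given as counts.

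The spread of signal sets the precision here, together with the small number of arrays. An oligo was called detected in a channel when the median over its 4 spots of signal minus background exceeded 2 SDs of the background. By this measure 19.8% to 63.7% of oligos were detected in the culture channel of an array and 15.0% to 67.2% in the reference channel. Spots brighter than 60000 were counted as saturated, and 45 oligos, 6 of them named, had such a spot on some array. For a gene not well above background on every array of one time, a bound of the form "at least N-fold" was computed from the culture channel after loess and Aquantile scaling, with all arrays as labelled or, for pyrF and where stated, without the second 690 min sample. It compares the brighter mean with the higher of the lowest detected signal on each array and the dim gene's own signal, and no fold is given where both times were dim. Such a bound holds for the culture signal, while the p-value beside it belongs to the ratio, and where the reference channel moved as well the bound can exceed the fold of the ratio.

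Background was corrected with limma's normexp method at an offset of 50, and each array was normalised with loess. Log2 ratios were averaged over the 4 spots, turned to culture over reference by the dye labels, freed of a dye bias per oligo taken from the 11 swapped pairs, and averaged per culture sample. The limma model had 6 time points and no other term, with 6 residual and 3.52 prior degrees of freedom, and one spread shared by all times. A moderated F test covered all times, and 6 contrasts covered 3120 against 690 min and the 5 consecutive steps. Adjusted p-values are Benjamini-Hochberg values from limma over all 2688 oligos, called below 0.05. The ratio of pyrF against 0 was tested in the same model, a test that leaves out the spread of the reference.

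Gene groups were 25 lists of symbols and product names. The 9 lists with at least 4 measured members were tested with camera against the other named genes, at a preset correlation of 0.01 and at an estimated one, and with fry, which tests a list against no change, with Benjamini-Hochberg adjustment over the 9 lists. These are pyrimidine synthesis and uracil use, purine synthesis, translation factors and aminoacyl-tRNA synthetases, the citric acid cycle, chemotaxis and sensory transducers, chaperones and proteasome, cobalamin synthesis, amino acid catabolism, and DNA replication and repair. List calls below are those of camera, and the results of fry are not given. Another 7 lists had 2 members each and are described by counts: ribosomal proteins, the respiratory chain, rhodopsins and their synthesis, arginine fermentation, DMSO and TMAO respiration, oxidative stress defence, and phosphate uptake. The members of the DMSO and TMAO list were moaC and moaA, of molybdenum cofactor synthesis, so no reductase gene was measured in it. The other 9 lists had 0 measured members. Plasmid-borne genes were planned as further lists and are not analysed here, because the oligos carry no locus number. Product names were not used here, so members were found by symbol alone. The members found for the translation list are all synthetases, so it is called by that name, and the measured translation factor gene infB, whose symbol the list lacks, is not in it.

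The rule for named genes takes, among called genes whose samples at one time all lie on one side of those at the other, the 12 largest rises and 12 largest falls from 690 to 3120 min and the 4 largest of each in every step, together with pyrF, all members of the pyrimidine list and up to 4 members of any list described. The tests, lists, rule and the settings listed next, save those said to be later, were fixed before the data were examined. Other genes are named where the text says that they were chosen after their values were seen.

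Other settings tried were no background subtraction, an offset of 16, median centring, scaling of the arrays, the authors' own values, a filter on dim oligos, no removal of dye bias, a model on single arrays, the array-number run as a block, trend and robust variance, the median over spots, and leaving out each sample. The ratios of the second 690 min sample ran against those of the other 11, so results are also given with its sign turned and with it left out, choices made after the data were seen. Array numbers fall into a run of 11 and a run of 12 arrays, each with 1 sample of each time. The deviations of samples of one run from their time means correlated at 0.114 to 0.464 over the 15 pairs of times, and the run served as a block.

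On simulated arrays of the same design for 3120 against 690 min, with 2688 oligos of which 200 were changed, the model recovered 37.3% of changes of 0.5 log2, 95.5% of 1 and 100% of 2. It made 167 calls, of which 12 (7.19%) were false. The simulated labels were all correct, the spread was preset and no run effect was included, so these rates need not hold for the real arrays. Versions were R 4.3.3, limma 3.58.1, version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.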

Results

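The arrays followed a pyrF deletion strain through growth with added uracil, from an optical density of about 0.2 at 690 min to about 1.1 at 3120 min. There were 12 culture samples, 2 at each of 690, 1200, 1860, 2280, 2760 and 3120 min, each set against a common reference RNA. Ratios are log2 of culture over reference, and changes between times are differences of these ratios with their limma standard error (SE). A bound of the form "at least N-fold" between 2 times compares the culture signal alone, so it can exceed the fold of the ratio where the reference channel moved too.

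The deleted gene pyrF was lower in the culture than in the reference in 11 of 12 samples. The 11 values ran from -1.24 to -0.69, with a mean of -0.92 (SD 0.16, n = 11; limma adjusted p = 3.69e-08). The second 690 min sample stood at 1.11, on the other side of 0 and with pyrF not well above background in either channel, and with it as labelled the mean was -0.75 (SD 0.60, n = 12; limma adjusted p = 9.67e-04). With its sign turned the mean was -0.93 (SD 0.16, n = 12; limma adjusted p = 3.02e-09), ranking 27 from the lowest among all oligos and 3 among the named ones. These p-values leave out the spread of the reference. The pyrF oligo was not well above background in the culture channel on any of the 22 arrays of the swapped pairs, and was above background in the reference channel on 16 of them. The mean ratios above thus rest on a dim culture signal. As a fold the culture is given only by a bound, at least 1.08-fold lower. Whether the oligo lies in the deleted part is not known here.

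**Figure D1:**
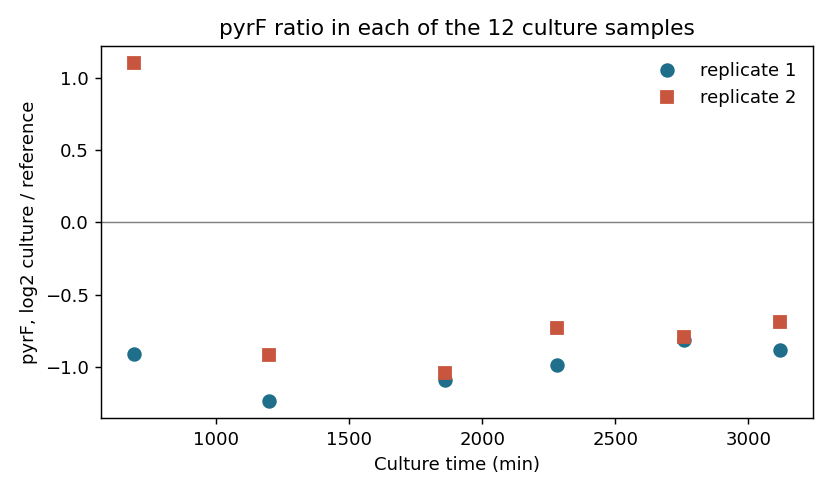
Log2 ratio of pyrF, culture over reference, in each of the 12 culture samples against culture time in min, with circles for replicate 1 and squares for replicate 2. The 690 min sample labelled replicate 2 lies at 1.11, and the other 11 lie between -1.24 and -0.69.

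That single-array sample correlated with the other 11 samples across oligos at r = -0.79 to -0.41, while those 11 correlated with one another at 0.37 to 0.94. Its dye direction is therefore not settled. Counts of oligos and list tests are given with all samples as labelled, with this sample turned, and with it left out, and single genes as labelled unless stated. Oligos are not independent replicates, so these correlations carry no p-value.

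Over the whole course, 42 named genes changed in the moderated F test. Among all 2688 oligos, 554 changed with the samples as labelled, 1208 with the doubted sample turned and 1089 without it, and 537 oligos, 39 of them named, were called in all 3 readings. Leaving out the first 690 min sample gave 1833 oligos, and leaving out a sample of any later time gave 264 to 380. The lowest counts came without the first (268) or second (264) sample of 1200 min, the first (297) or second (321) of 1860 min, the first (335) or second (345) of 2280 min, the first (340) of 2760 min and the first (361) of 3120 min.

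Comparing the end of the course with its start asks which genes differ between dense and early cultures. Of 49 named genes called, 33 were lower at 3120 min and 16 higher. As labelled, among genes well above background at both times, the ribosomal protein genes had the largest falls: rpl12p, encoding ribosomal protein L12, fell by 1.50 (SE 0.15; limma adjusted p = 3.41e-04) and rpmC, encoding ribosomal protein L29, fell by 1.31 (SE 0.18; limma adjusted p = 0.00138). The succinyl-CoA synthetase genes sucC and sucD fell by 0.98 and 0.89, the enolase gene eno by 0.96 and secY, of the protein translocation channel, by 0.88. In culture signal, the lysyl-tRNA synthetase gene lysS was at least 1.96-fold lower, hisF of histidine synthesis at least 2.12-fold lower and infB, encoding a translation initiation factor, at least 1.48-fold lower, since none was well above background at 3120 min. Without the doubted sample these bounds were 1.99 for lysS, 2.25 for hisF and only 1.19 for infB. The ratio of infB fell by 0.98 as labelled and by 0.56 without that sample. The glutamyl-tRNA reductase gene hemA fell by 1.01, detected at 3120 min on 3 of 4 arrays. The tRNA splicing gene endA was called as lower, with no fold given, as it was detected on 1 of 3 arrays at 690 min and 0 of 4 at 3120 min. The aldolase gene deoC, at -1.39, was not well above background at either time.

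Among the rises, argH, encoding argininosuccinate lyase, had a culture signal at least 4.85-fold higher at 3120 min, and at least 6.64-fold higher without the doubted sample. Its ratio, which the reference channel also moves, rose by 1.44 (limma adjusted p = 0.0199), by 2.16 without that sample and by 0.73 without the first 690 min sample. The glutamate dehydrogenase gene gdhB rose by 0.81, with saturated spots on 8 arrays, and the transducer genes htr8 and htr1 rose by 0.79 and 0.59. The stress ferritin gene dpsA rose by 0.62, the phosphate regulator gene phoU by 0.67, purE of purine synthesis by 0.72 and serB of serine synthesis by 0.58. Of these, htr1, purE and serB were each detected on 1 of 3 arrays at 690 min, and on 4, 1 and 3 of 4 at 3120 min. The histidine degradation genes hutU, hutI and hutG had changes of 0.95, 0.89 and 0.86, and trpC of tryptophan synthesis 0.53, but these 4 were not well above background at either time. With the doubted sample turned, purE (0.20, limma adjusted p = 0.235), trpC (0.25, limma adjusted p = 0.115) and deoC (-0.41, limma adjusted p = 0.139) were no longer called, and without it trpC and deoC were not (limma adjusted p = 0.0626 and 0.112). The other 21 of the 24 kept their call and direction in both readings, though several sizes moved. With the sample turned, rpl12p fell by 1.34, rpmC by 1.32, sucD by 0.97, sucC by 0.96, eno by 0.85, hemA by 0.73 and secY by 0.70, while dpsA rose by 0.90, serB by 0.76, htr8 by 0.50, gdhB by 0.48, htr1 by 0.47 and phoU by 0.36. Without it purE stood at 0.42 and phoU at 0.38.

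Of the 24 genes, rpl12p, rpmC, hemA, sucC, sucD, eno, lysS, hisF, htr8 and hutU passed under every alternative that gave a value. In all, 808 oligos changed from 690 to 3120 min, 373 higher and 435 lower. Turning the doubted sample gave 1174 (534 higher, 640 lower) and leaving it out 995, and 590 oligos, 39 of them named, were called the same way in all 3 readings. Without the first 3120 min sample the count was 292, without the second 382, and without the first 690 min sample 1707. Without the first 3120 min sample 13 of the 24 genes were not called, and without the second 5, argH, phoU, dpsA, serB and deoC in both cases. Of the calls, 759 were unnamed oligos. With the authors' own ratios, 76.3% of the calls were higher, against 46.2% here and 36.1% after median centring, and the median of all oligos then lay at 0.28. With the array run as a block the count was 913.

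Some genes passed only in the other 2 readings and are named after their values were seen. The malate dehydrogenase gene mdh fell by 1.29 with the doubted sample turned and by 1.17 without it, and gdhA1, a glutamate dehydrogenase gene, by 1.04 and 0.97, mdh being detected at 3120 min on 1 of 4 arrays. As labelled their changes were -0.31 and -0.44. The halorhodopsin gene hop, encoding a light-driven chloride pump, rose by 0.82 with the sample turned (0.48 as labelled) and by 0.81 without it, where its culture signal was at least 3.51-fold higher.

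Of the 12 synthetase genes, 6 fell from 690 to 3120 min and 0 rose, and 10 fell adjusted over the list alone. Among the 6 were lysS, cysS and glyS, not well above background at 3120 min, and serS (-0.65), detected there on 1 of 4 arrays. The mean change was -0.46 (camera adjusted p = 0.00711, adjusted p = 0.159 with an estimated correlation). With the doubted sample turned or left out, 8 fell and the list was not called (camera adjusted p = 0.0973 and 0.0554). Of the 13 chemotaxis and transducer genes, 3 rose (htr8, htr1 and htr18, the last not well above background at either time) and 0 fell, also adjusted over the list alone, with a mean of 0.50 (camera adjusted p = 1.96e-04, adjusted p = 0.284 with an estimated correlation). With the sample turned, 6 rose and htr4, not well above background at 3120 min, fell, the mean was 0.14 and camera's adjusted p 0.0694, and without it 4 rose and 1 fell (camera adjusted p = 0.0554). The list's cheA, cheY and cheB stood at 0.87, 0.81 and 0.83 as labelled, and at 0.08, 0.18 and 0.28 with the sample turned.

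Of 7 amino acid catabolism genes, gdhB, hutU, hutI and hutG rose and gdhA2 fell by 0.58 (detected at 3120 min on 2 of 4 arrays), the same counts adjusted over the list alone, with a mean of 0.41 (camera adjusted p = 0.0286, adjusted p = 0.159 with an estimated correlation). The 3 hut genes were near background and gdhB had saturated spots, as said above. With the sample turned or left out, 4 rose and 2 fell and the list was not called (camera adjusted p = 0.159 and 0.126). Of 5 citric acid cycle genes, sucC and sucD fell (3 adjusted over the list alone), at a mean of -0.57 (camera adjusted p = 0.0938, or 0.0973 turned and 0.0708 without the sample, with 3 fallen in both). Of 8 pyrimidine genes, dcd fell, and its culture signal was at least 1.14-fold lower without the doubted sample. As labelled, pyrB (-0.16), pyrI (-0.11) and cmk (-0.64) did not pass, nor did carA (0.19), carB (-0.13), tmk (-0.18) and pyrF (-0.89), which were not well above background at 3120 min. The gene carB was lower and called in the other 2 readings (limma adjusted p = 9.52e-05 turned and 7.99e-04 without the sample). The pyrF value rests on the doubted sample, and stood at 0.22 with it turned and 0.12 without it. In the same 2 readings cmk stood at -0.19 and -0.19, and carA at -0.23 and -0.14, on the other side of 0. The list as a whole was not called (1 fell adjusted over the list alone; camera adjusted p = 0.534), nor with the sample turned or left out, where 2 fell (camera adjusted p = 0.512 and 0.505). Of 7 purine genes purE rose and guaB fell, of 6 chaperone and proteasome genes dnaJ fell, and of 4 cobalamin genes cbiT fell. Adjusted over the list alone, 1 purine gene rose and 1 fell, 1 chaperone gene rose and 2 fell, and 1 cobalamin gene fell. None of 8 DNA replication and repair genes passed, also adjusted over the list alone. Camera's adjusted p was 0.534 for the purine and the chaperone lists, 0.383 for cobalamin and 0.993 for DNA. With the sample turned, 2 purine genes rose (camera adjusted p = 0.0973), 1 chaperone gene rose and 2 fell (0.729), 4 cobalamin genes fell (0.146), and 1 DNA gene rose and 3 fell (0.937). Without it, 2 purine genes rose (camera adjusted p = 0.0554), 1 chaperone gene fell (0.835), 2 cobalamin genes fell (0.157) and 3 DNA genes fell (0.835). Among the 2-member lists, both ribosomal genes fell, both oxidative stress genes rose (dpsA and msrA), sdhC of the respiratory chain fell and phoU of phosphate uptake rose. The rhodopsin, arginine fermentation and DMSO lists had 0 calls as labelled. In each of the other readings hop and bat of the rhodopsin list rose. However, bat was not well above background at either time. Its separate array runs as labelled gave -0.49 and 1.14, and the -0.49 rests on the doubted sample. Of the 2 cofactor genes in the DMSO list, 1 fell with the sample turned. No camera call in any comparison held with an estimated correlation.

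The first step, from 690 to 1200 min, gave different results in the 3 readings. With all samples as labelled, limma called 0 oligos, 250 had an unadjusted p below 0.05, and the model on single arrays called 11. With the doubted sample turned, thiD and thiC, both of thiamine synthesis, rose by 1.50 and 0.95, and the culture signal of thiC was at least 8.37-fold higher without that sample, where its ratio rose by 0.94. Another thiamine gene, thiL, was not called (-0.23 with the sample turned, limma adjusted p = 0.169). The purine gene purL rose by 0.75, while arcC and arcA, which encode arginine fermentation enzymes, fell by 1.28 and 0.55, and gdhA1 fell by 0.45. At 690 min thiD and purL were each detected on 1 of 3 arrays. The calls of argH, as higher, and gdhA1 were made only with the sample turned (limma adjusted p = 0.116 and 0.183 without it), and argH was detected on 0 of 3 arrays at 690 min and 1 of 4 at 1200 min. All these genes are named after their values were seen. As labelled, thiD stood at 0.81, thiC at 0.79, purL at 0.65, arcC at -1.01, arcA at -0.52 and gdhA1, on the other side of 0, at 0.16. Of the pyrimidine list, carB was called only without the sample (0.77, limma adjusted p = 0.0311). It stood at 1.55 as labelled and 0.58 turned (limma adjusted p = 0.358 and 0.0681), and was detected on 1 of 3 arrays at 690 min.

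The count of calls was 26 with the sample turned (16 higher, 10 lower; 47 with the run as a block) and 20 without it. Leaving out the first 690 min sample instead gave 1297. Of the gene lists, purine synthesis was called only with the sample turned (mean 0.34, camera adjusted p = 0.0304, adjusted p = 0.590 with an estimated correlation) or left out (mean 0.43), with 1 member risen. Without the doubted sample, its members purB, purD and purF were not well above background at either time, nor was purM at 690 min.

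As labelled, the step from 1200 to 1860 min brought the largest fall in ratio of any named gene called, though that gene was not well above background at 1860 min. The gene carB, encoding the large subunit of carbamoyl-phosphate synthetase at the start of pyrimidine and arginine synthesis, had a culture signal at least 5.58-fold lower at 1860 min. Its ratio, which the falling reference signal also moves, changed by -1.88 (SE 0.38; limma adjusted p = 0.0211), with changes of -1.86 and -1.90 in the separate array runs. With the doubted sample turned the change was the same, at a limma adjusted p of 2.51e-05. The ribosomal genes rpmC and rpl12p fell by 0.99 and 0.83, and lysS fell by 0.81 (SE 0.10; limma adjusted p = 0.00558). The proteasome-activating nucleotidase gene pan1 rose by 0.84, the transducer gene htr1 by 0.55, the sensory rhodopsin I gene sop1 by 0.50 and arcA by 0.42. At 1200 min pan1 and sop1 were each detected on 1 of 4 arrays, and lysS, htr1 and arcA on 3 of 4, and at 1860 min lysS and sop1 on 3 of 4.

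These 8 genes are among 12 named ones called, the others being sucC (-0.68), eno (-0.64), hisF (-0.62) and sucD (-0.59), and 4 rose and 8 fell in all. The count over all oligos was 192, 102 higher and 90 lower, of which 180 were unnamed. It was 669 with the doubted sample turned (318 higher, 351 lower) and 663 without it, with 191 called the same way in all 3 readings, and 231 with the array run as a block. Leaving out the first or second 1200 min sample gave 13 and 0, the first or second 1860 min sample 0 and 16, and either 2280 min sample 101. Of the 8 genes, lysS alone stayed called without the first 1200 min sample, and none without the second or without either 1860 min sample, where the limma adjusted p of carB was 0.134 to 0.153. Without either 2280 min sample pan1, htr1, sop1 and arcA were not called, without either 2760 min sample sop1 and arcA, and without either 3120 min sample htr1, sop1 and arcA. Without the first 690 min sample 663 were called. The fits that leave out a sample of a later time keep the doubted sample as labelled, and it enters the spread shared by all times. After median centring 39.3% of the calls were higher, against 53.1% here. With the turned sample, carA (-0.44) and dcd (-0.41) of the pyrimidine list fell as well, and hop (0.51), argH (0.72), phoU (0.57) and arcC (0.54) rose, as did bat, detected on 0 of 4 arrays at 1200 min and 1 of 4 at 1860 min. Of 4 arrays, argH was detected on 1 and hop and dcd on 2 at 1200 min, and carA and dcd on 1 at 1860 min. None of these 7 was called as labelled, where their sizes of change were the same, and they are named after their values were seen.

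The chemotaxis list was called, with htr1 and sop1 risen (3 risen adjusted over the list alone) and a mean of 0.23 (camera adjusted p = 0.00993, adjusted p = 0.409 with an estimated correlation); turned or without the sample, 5 of 13 rose (camera adjusted p = 0.00116 and 0.00157). The synthetase list had lysS fallen (2 fallen adjusted over the list alone) and a mean of -0.27 (camera adjusted p = 0.0278, adjusted p = 0.296 with an estimated correlation), and was not called with the sample turned (camera adjusted p = 0.0729) or left out (0.0628). In the citric acid cycle list 2 genes fell as labelled and 3 in the other readings, and in the pyrimidine list 1 and 3.

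**Figure D2:**
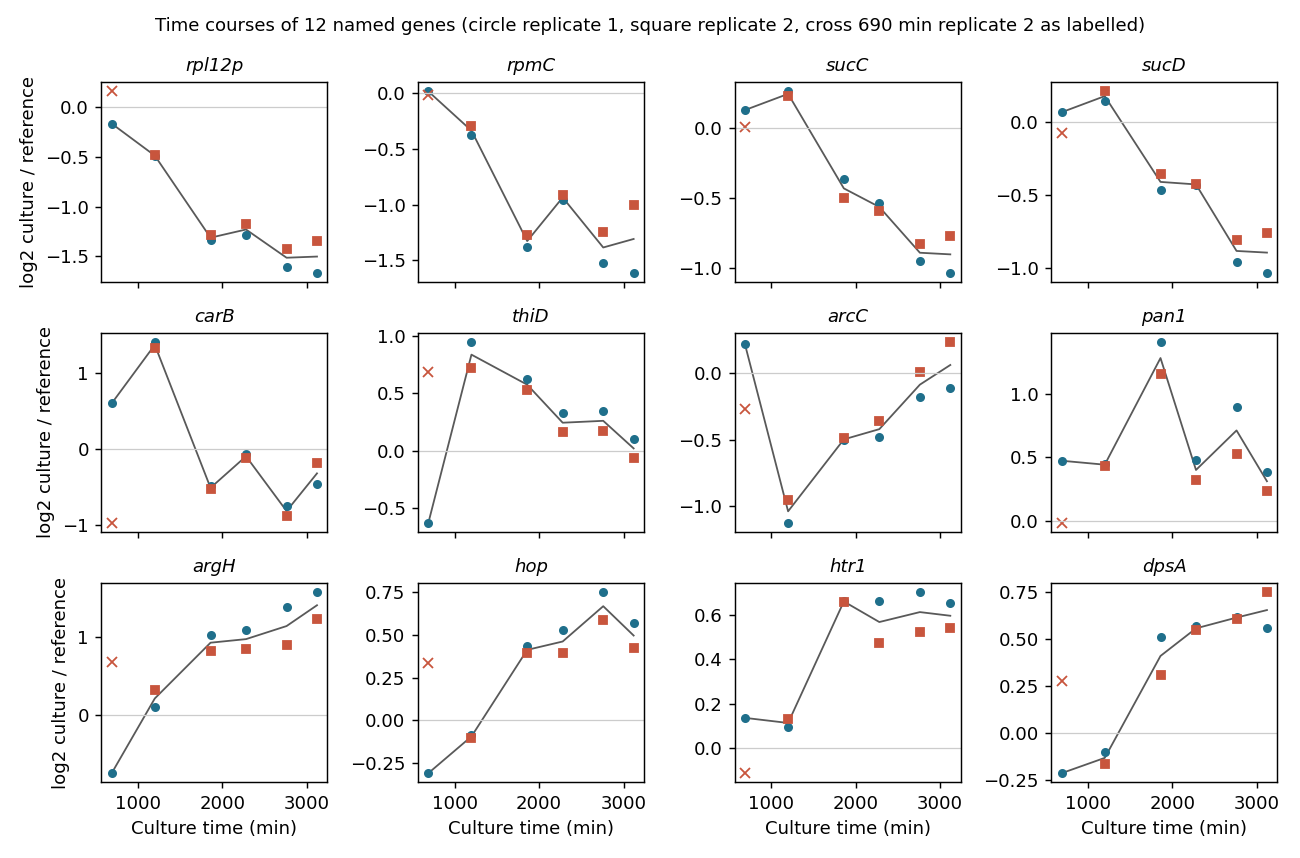
Log2 ratios, culture over reference, of 12 named genes against culture time in min, with circles for replicate 1, squares for replicate 2, a cross for the second 690 min sample as labelled, and a line through the means, which leaves that sample out. The gene carB fell by 1.88 from 1200 to 1860 min, and rpl12p fell by 0.83.

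**Figure D3:**
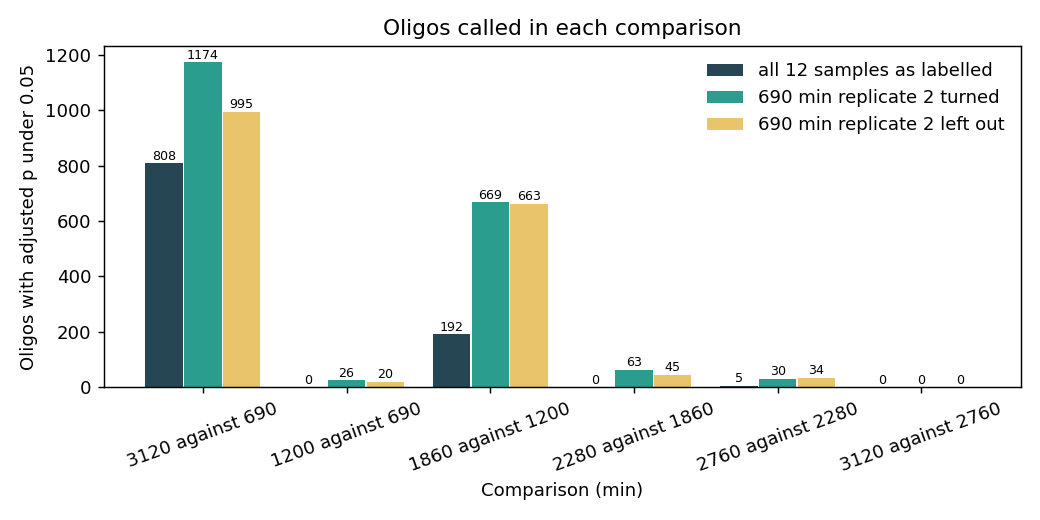
Number of oligos with a limma adjusted p under 0.05 in each of the 6 comparisons, as bars for the samples as labelled, with the second 690 min sample turned, and with it left out. The comparison of 3120 with 690 min gives 808, 1174 and 995, and the last step gives 0 in all 3.

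The later steps held fewer changes in named genes, but they were also shorter. They lasted 7, 8 and 6 hours, with gains in optical density of 0.0755, 0.1415 and 0.169. The step from 1200 to 1860 min lasted 11 hours, with a gain of 0.2895. From 1860 to 2280 min no named gene passed as labelled. In the steps from 1200 min on, the sizes of change are the same in all 3 readings, and only the spread and thus the calls differ. With the doubted sample turned, pan1 was called at a fall of 0.88, with a culture signal at least 3.0-fold lower without that sample. The glutamine synthetase gene glnA was called at a fall of 0.53, serS at a fall of 0.46 and folP of folate synthesis at a rise of 0.37. The gene panB, of a second proteasome-activating nucleotidase, was called too, and its culture signal was at least 1.16-fold lower without that sample. Without it pan1 and glnA stayed called, while serS, folP and panB did not (limma adjusted p = 0.0630, 0.0621 and 0.0656). Of 4 arrays, serS was detected on 3 at 1860 min and 2 at 2280 min. As labelled limma called 0 oligos, with 147 at an unadjusted p below 0.05 and 33 by the model on single arrays. The count was 63 with the sample turned (23 higher, 40 lower) and 45 without it.

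From 2280 to 2760 min, the cobalamin list was called as labelled at a mean of -0.25 (camera adjusted p = 0.00566, adjusted p = 0.113 with an estimated correlation). The amino acid catabolism list was called at a mean of 0.17 (camera adjusted p = 0.0205, adjusted p = 0.113 with an estimated correlation). As labelled no member of either list passed, adjusted over the list alone included. In the amino acid catabolism list hutG, hutI, hutU and glyA were not well above background at either time. With the sample turned and left out, the camera adjusted p was 0.0114 and 0.0143 for cobalamin, and 0.125 and 0.0787 for amino acid catabolism. With the sample turned, hisF fell by 0.40 (detected on 3 of 4 arrays and then 2 of 4), a call not made without the sample (limma adjusted p = 0.0549). In both of these readings carB was called, and without the sample hutU (0.40, limma adjusted p = 0.0380), but hutU and carB, at -0.72, were not well above background at either time. As labelled limma called 5 oligos, 2 higher and 3 lower, all unnamed, and 30 with the sample turned (60 with the run as a block) and 34 without it. Leaving out single samples gave 0 to 34.

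From 2760 to 3120 min no list or named gene passed. Limma called 0 oligos in all 3 readings, with 43, 174 and 184 at an unadjusted p below 0.05 as labelled, turned and without the sample. The model on single arrays also called 0.

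The reference channel moved along with the culture channel for many oligos, and for some genes the ratio then changed less than the culture signal did. From 1200 to 1860 min, carB fell from 12.18 to 8.68 in the culture channel and from 10.81 to 9.19 in the reference channel, in log2 signal. From 690 to 3120 min, argH rose from 8.46 to 12.38 in the culture channel and from 9.20 to 10.97 in the reference channel. Over the same times hop rose from 9.30 to 11.58 and from 9.61 to 11.09. From 690 to 1200 min, thiC rose from 9.09 to 12.83 in the culture channel and from 9.23 to 12.03 in the reference channel. From 1860 to 2280 min, pan1 fell from 11.52 to 8.97 and from 10.24 to 8.57. All these values leave out the doubted sample. The gene rpl12p did not show this: from 1200 to 1860 min it fell from 14.11 to 13.31 in the culture channel and stood at 14.59 and 14.63 in the reference channel. Across oligos passing the brightness filter, the reference change from 1200 to 1860 min correlated with the culture change at r = 0.90, with a slope of 0.54.

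**Figure D4:**
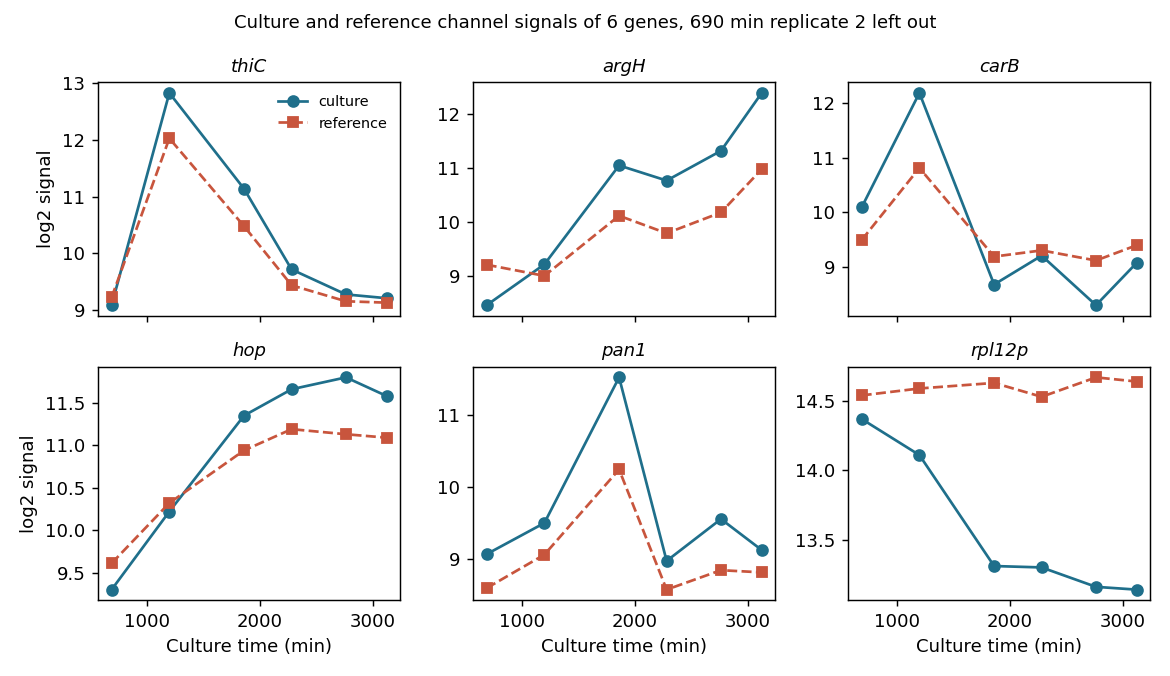
Log2 signal of the culture channel (circles) and the reference channel (squares) for 6 genes against culture time in min, without the second 690 min sample. The argH signal in the reference channel rises from 9.20 to 10.97 while that in the culture channel rises from 8.46 to 12.38.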

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

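The readings with the second 690 min sample turned, alone or with the run block, and the list tests without it were chosen only after its values were seen. The other alternatives were planned. Of 32 calls of named genes, 10 kept their call and direction under all alternatives and 22 lost it under at least 1. Over all settings 677 values stayed on their side of the threshold, 114 fell short of it and 1 turned: deoC from 690 to 3120 min stood at 0.032 with the authors' values, and the cause was not tested. Among the list tests 290 stayed, 32 fell short and 2 passed anew. The mean pyrF ratio stayed past the threshold throughout, from -1.05 to -0.58. Signal over background limits the rest: 29 of 133 named genes were not well above background at either 690 or 3120 min, and 44 at either 2760 or 3120 min.

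The cause of the following moves was not tested. Counts in the F test were 311 after scaling the arrays, 920 with single arrays, 1208 with the sample turned and 1391 with it turned and the run as a block. For 3120 against 690 min they were 369 after scaling, 1275 with the authors' values (973 higher, 302 lower) and 1293 turned with the block. For 1200 against 690 min they were 5 after scaling, 3 with the authors' values, 11 with single arrays, 26 turned and 47 turned with the block. For 1860 against 1200 min they were 115 with trend and robust variance, 417 with single arrays, 669 turned and 809 turned with the block. For 2280 against 1860 min they were 9 without background subtraction, 7 without dim oligos, 33 with single arrays, 63 turned and 89 turned with the block. For 2760 against 2280 min they were 16 without background subtraction, 3 at the smaller offset, 0 after median centring, after scaling and without dim oligos, 2 with the authors' values, 18 with single arrays, 30 turned and 60 turned with the block. By limma with these samples as labelled, 139 oligos of that last step had an unadjusted p below 0.05.

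The replicate block, the run of array numbers, gave 662, 913, 0, 231, 0, 4 and 0 calls with the samples as labelled, in the order F test, 3120 against 690 min and the 5 steps, and it kept all 32 calls of named genes followed here, while 58 named genes in place of 49 were called for 3120 against 690 min. Leaving out 1 sample at a time gave 264 to 1833 calls in the F test, 292 to 1707 for 3120 against 690 min, and 0 to 1297, 0 to 663, 0 to 45, 0 to 34 and 0 to 0 for the steps, and the lone sample of a time is then assumed to vary like the rest. The mean of pyrF ran from -0.92 to -0.58.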

Other observations

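All tests of the reference, of the odd 690 min sample and of the reference channel were chosen only after the results were seen, while the tests of neighbouring genes were written down before theirs.

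Named genes that lie next to each other on the chromosome had similar time courses. In the gene order of strain 91-R6 there were 20 neighbouring pairs among the 133 named genes, and 13 of them correlated above 0.5 over the 6 time means without the odd sample. The succinyl-CoA synthetase genes sucC and sucD correlated at r = 0.99, hutU and hutG of histidine degradation at 0.99, cheB and cheY of chemotaxis at 0.97, arcC and arcA of arginine fermentation at 0.95, htr1 and sop1 of light sensing at 0.94 and carB and carA at 0.91. Of these, hutU and hutG were not well above background in the culture channel at any time. The pair gatC and gatA, of a tRNA amidotransferase, went apart at -0.98. The gene order is that of a related strain.

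The mean correlation of the 20 pairs was 0.599, against 0.056 over all pairs (one-sided permutation p = 3e-05, 100000 permutations). The oligos of neighbours also lay closer together in the reading order of the array, at a mean of 255.6 positions against 836.1 (one-sided permutation p = 1e-05, the smallest these permutations can give). Place in that order is thus a candidate explanation. Positions count oligos along the rows of the slide, so they are not physical distances. Against place in that order alone, 337 close pairs of genes that are not neighbours had a mean r of only 0.0855 (one-sided permutation p = 0.21). At most 16 positions apart, 117 pairs that are not neighbours had a mean of 0.147 (one-sided permutation p = 0.076) and 13 neighbouring pairs a mean of 0.783, a comparison made after these results were seen. The 5 neighbouring pairs lying over 200 positions apart had a mean of 0.306. Leaving out gatC and gatA, a choice made after their value was seen, since gatC was well above background in the culture channel on none of the arrays of the swapped pairs, gave 0.626 for the other 4, and these few pairs decide nothing. The same rule was not applied to the close pairs: hutU, hutG and hutI were well above background on none of these arrays either. Their pairs stayed in the mean of 0.783. Place in reading order as the whole cause is argued against by the close pairs that are not neighbours, while a part of it is not excluded. Effects of physical distance on the slide were not tested. Shared transcription was not tested and stays open.

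The second 690 min sample ran against every other sample. A gene-wise dye bias is argued against, since the correlation with the first 690 min sample was -0.77 before and -0.79 after its removal. Exchanged dye labels may account for it: the opposite correlation was stronger with the first 690 min sample than with any later sample by 0.0844, where the 2 samples of a later time differed by at most 0.0450. A culture in another, opposite state stays open too. The deleted gene pyrF could have decided, but on this array its signal lay 1.42 SDs above background in the labelled culture channel and 0.376 in the reference channel, both under the 2 SDs needed. Every array of the swapped pairs with the culture in Alexa 546 had pyrF above background in its reference channel. This array, with the same dye label, did not. With the culture in the other dye, only some arrays of the swapped pairs had pyrF above background in the reference channel. A miss would thus be less unusual under exchanged labels, but a single array near background decides nothing. These explanations cannot be told apart here, and no biological explanation was given by the design to be tested.

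The reference channel moved with the culture channel. Differences in hybridisation shared by both channels are argued against as the whole cause. The reference change correlated with the ratio change at 0.573 from 1200 to 1860 min, at 0.149 from 690 to 1200 min and at 0.348 to 0.597 in the other comparisons. A part from such differences stays open. From 2760 to 3120 min, a step without calls, the reference change still correlated with the culture change at r = 0.914 (slope 0.699). Signal of one dye read in the other channel stays open, since the comparisons differ. From 1200 to 1860 min, the reference channel held a share of 0.457 of the culture's change where the ratio rose and 0.0339 where it fell. From 690 to 1200 min the share where the ratio rose was as low as -0.00542 in one dye orientation (quartiles -0.660 and 0.289 over 32 oligos). Where it fell, the share was 0.236 from 690 to 3120 min and 0.356 from 1860 to 2280 min. Another reference RNA on the arrays of each time stays open as well, since the reference change from 1200 to 1860 min, the only step compared in this way, agreed between dye orientations at r = 0.749 and between runs at 0.602. These cannot be separated here, and no biological explanation was tested.

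The pyrF oligo was above background in the reference channel on 72.7% of the 22 arrays of the swapped pairs. The root mean square log2 ratio of culture over reference was 0.316 at 1200 min, its smallest mean, 0.346 at 690 min and 0.598 at 3120 min.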
